A study of Mus musculus with 9 samples.

How the data were processed

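The series holds mouse T cells measured by mRNA sequencing and by small RNA sequencing. Per the labels' protocols, CD4+CD25− T cells were taken from the spleen and lymph nodes of C57BL/6 mice by negative selection against CD8, NK1.1, CD25, Ter119, CD19 and the γδ T cell receptor. They were then cultured with mature dendritic cells at a ratio of 4 T cells per dendritic cell, with IL-2 at 50 ng/mL, for 7 days, and sorted by flow cytometry. Double negative T cells (DNT) were CD3+CD4−CD8−NK1.1−, activated CD4 cells were CD3+CD4+CD8−NK1.1−, and naive CD4 cells were CD3+CD4+CD25−. Every sample carries the same culture protocol, so the labels do not say whether the naive cells were taken before culture. Each population has 2 mRNA libraries and 1 small RNA library. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

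The authors deposited 1 table of FPKM values (reads per kilobase of gene, scaled to the library's total) for 41128 genes and 1 table of miRNA read counts and TPM values for 993 miRNAs. Per the submitters' processing notes, the tools were Bowtie2 2.0.6, TopHat2 2.0.9 and HTSeq 0.6.1 and the genome build was mm8, with no roles stated. How reads shared between near-identical genes were counted, and whether strand was used, is not given in the sources used here. Values of gene families with close copies (the Klra receptors, Gzmc to Gzmg, the Tcrg constant regions, Ly6c1 and Ly6c2) are therefore uncertain as to the member. The deposited FPKM values of a gene are whole multiples of what 1 read is worth. Library totals were recovered from these steps, and 118575 of 119375 values above 0 (99.33%) came out as whole reads within a relative tolerance of 2e-08. Where a gene's reads and its length share a divisor, the recovered reads are divided by it. The deposited miRNA counts are whole reads, and the authors' TPM equals CPM, the counts scaled to the same library total (largest difference 4.1e-10), so it carries no correction for length. Gene symbols came from a table of gene identifiers, which matched 40254 of the 41128 identifiers. No genome was used, and no coordinates are given.

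For mRNA, log2(FPKM + 1) was fitted with limma (trend in the prior variance) over all 6 libraries with 1 coefficient per group, after keeping genes with a mean FPKM of at least 1 over the 6 libraries, which left 12414. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Tests were two-sided, and adjusted p-values are limma's with Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were DNT against activated CD4, DNT against naive CD4 and activated CD4 against naive CD4. A gene counted as higher (or lower) in DNT than in both CD4 populations where both comparisons called it in that direction.

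The groups, tests, gene lists, named-gene rule and all but 2 of the alternative settings were chosen before the data were examined. The 35 gene lists cover T cell lineage and function, cell cycle, metabolism, stress and markers of other cell types. The 34 lists with at least 5 tested genes were tested with camera (limma) at a preset correlation between genes of 0.01, with an estimated correlation as an alternative, and with fry, which asks whether a list's genes move one way on balance. Adjusted p-values of lists are limma's, with Benjamini-Hochberg adjustment over the 34 lists of a comparison. Each list's calls were also counted with p-values adjusted over the list alone.

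Genes were named by rule. For DNT against activated CD4 these are the 15 largest rises and the 15 largest falls among called genes with a mean FPKM of at least 5 in the higher group and no overlap between the libraries of both groups. The other comparisons use 10 in each direction. Predicted genes, genes named only by number, immunoglobulin and T cell receptor segments, ribosomal protein genes and histone genes were left out. Genes of the sort markers, called members of each list with the largest absolute fold change first (up to 4 per list) and listed targets of miRNAs are named besides. Other genes named in the text were chosen after their values were seen, and are said to be so where they appear.

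With 1 small RNA library per population there is no replicate check and no test between populations. Each comparison sets 2 libraries against each other, not conditions. miRNAs with at least 100 reads in 1 of the 2 libraries were compared by the ratio of TPM, with an exact (Clopper-Pearson) 95% interval of the ratio that covers counting error only. A miRNA was described as higher or lower where the ratio was at least 2 either way and the interval excluded 1. Sequencing reads without molecular identifiers are not independent molecules, so these intervals are too narrow for the difference between cell preparations. The 8 largest ratios in each direction among miRNAs with at least 1000 reads in 1 of the 2 libraries are named, with the 10 most abundant miRNAs per library and members of 16 miRNA lists. The median of each miRNA list was placed among 10000 random lists of its size matched on abundance, as a description of these libraries. Of the 993 miRNAs, 16 are predictions. A limit of 3 reads, which a count of 0 allows, stands at 0.598 TPM in DNT, 0.762 in activated CD4 and 0.643 in naive CD4.

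On simulated data for DNT against activated CD4 with 200 changed genes among 11801, limma called 0 of 67 genes changed by 0.5 (log2), 6 of 64 changed by 1 and 51 of 65 changed by 2, with 3 unchanged genes called. edgeR's quasi-likelihood test on reads called 1, 13 and 53 of these, with 7 unchanged genes. Of 30 simulated lists of 20 genes, 5 were raised by 0.5. camera with the preset correlation called all 5 and 1 unchanged list, camera with an estimated correlation called 0 of the 5, and fry called 1 of the 5. The simulated genes were drawn independently, whereas estimated correlations of the real lists ran from −0.192 (B and plasma cells) to 0.84 (oxidative phosphorylation). The simulation therefore cannot show how often the preset correlation calls unchanged lists of correlated genes. In 100 simulated pairs of small RNA libraries with 254 miRNAs, the 95% interval held the true ratio in 95.3% of cases. Their counts varied by counting error alone, as the interval assumes. This checks the calculation and not the coverage for real cell preparations.

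The settings tried in place of these were a pseudocount of 0.1, no filter and a filter at FPKM 5, rescaling to TPM, median-of-ratios, trimmed mean of M-values and quantile scaling, a replicate block, limma without trend and with robust variances, fits to the libraries of 2 groups alone, leaving out each library in turn, an adjusted p under 0.01 and a minimum of 2-fold. Where a left-out library leaves its group with 1 sample, that sample is assumed to vary like the other groups. For miRNAs, the alternatives were median-of-ratios and trimmed mean scaling, CPM of the listed reads, minimums of 20 and 1000 reads and a ratio of 1.5. The CPM setting is the same as the main one, since TPM equals CPM here, so it could not change a result. edgeR's quasi-likelihood test on the recovered reads, and miRNA totals without the reads of miR-21a-5p, were added after seeing the data. A search for miRNA seed sites was planned and not run, because no transcript sequences were at hand. Depth was 23263592 to 31249030 reads per mRNA library and 3938307 to 5017781 reads per small RNA library. The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.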

Results

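The data set comprised 6 mRNA libraries and 3 small RNA libraries from mouse T cells of spleen and lymph node. Double negative T cells (DNT), which carry CD3 without CD4, CD8 or NK1.1, were compared with activated CD4 T cells and with naive CD4 T cells, which were sorted as lacking CD25. Each population had 2 mRNA libraries. Expression values below are FPKM, where ± gives the SD of n = 2, and ± after a log2 change gives its SE from limma. Recovered library totals were 31249030 and 27575590 reads for DNT, 24402264 and 25230700 for activated CD4, and 23263592 and 23885973 for naive CD4. Between 19601 and 20267 genes were above 0 per library. The 10 most abundant genes held 7.25% and 7.63% of the reads in DNT, 4.93% and 5.48% in activated CD4, and 4.50% and 4.30% in naive CD4. Replicates correlated at r = 0.984 in DNT, 0.982 in activated CD4 and 0.976 in naive CD4 across genes, and differed by more than counting noise. The first principal component held 76.2% of the variance and set naive CD4 apart from DNT and activated CD4. The second held 15% and separated DNT from activated CD4.

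The genes of the sort markers were read first. Cd4 (ENSMUSG00000023274) stood at 7.56 and 3.40 FPKM in the DNT libraries, at 478 and 499 in activated CD4 and at 726 and 629 in naive CD4. Its log2 change in DNT was −6.32 ± 0.29 (SE) against activated CD4 (limma adjusted p = 0.00124) and −6.79 against naive CD4 (adjusted p = 3.03e-05). The CD3 genes Cd3d, Cd3e and Cd3g were above 195 FPKM in every library, with log2 changes of −0.05, 0.11 and −0.16 in DNT against activated CD4 that did not pass the test (adjusted p = 0.908, 0.730 and 0.743). Cd8b1 fell by 1.38 (adjusted p = 0.0189), a call that ended without DNT replicate 2 or either activated CD4 replicate (0.0793 to 0.0854). Cd8a differed between the DNT replicates, at 4.74 and 112.7 FPKM, and its log2 change of 2.99 ± 1.33 against activated CD4 did not pass (adjusted p = 0.223, or 0.0135 without DNT replicate 1). Klrb1c, which encodes NK1.1, stood at 47.2 and 23.2 FPKM in DNT, 0.566 and 5.06 in activated CD4, and 2.61 and 7.77 in naive CD4. Its rise of 3.47 ± 0.72 against activated CD4 passed (adjusted p = 0.0278) but not with edgeR (0.0684) or without either DNT replicate, activated CD4 replicate 1 or either naive CD4 replicate (0.0519 to 0.106). Il2ra, which encodes CD25, was at 8.23 and 23.8 FPKM in naive CD4 and rose by 4.64 in DNT (adjusted p = 0.000352) and 5.67 in activated CD4 (adjusted p = 0.000249).

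**Figure D1:**
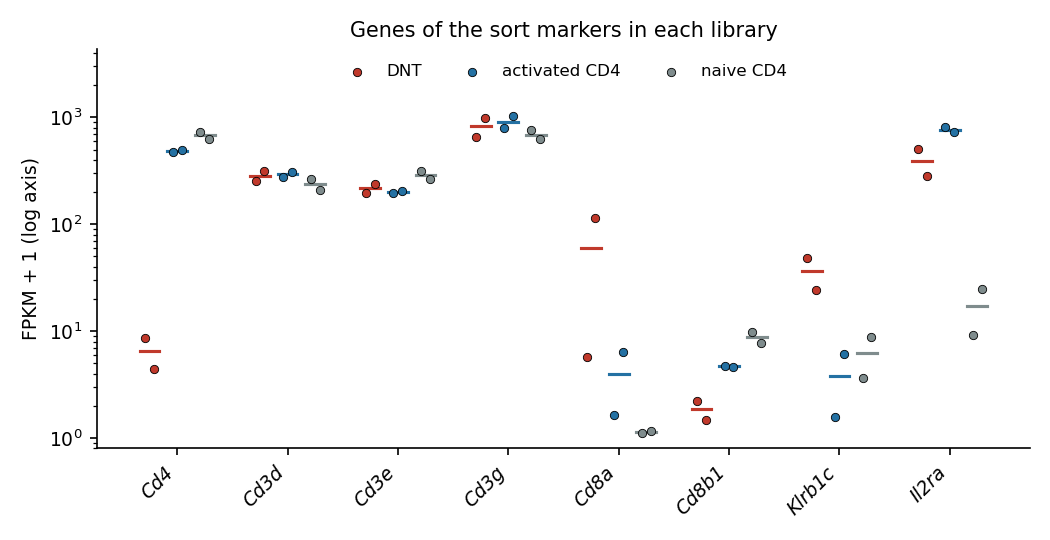
FPKM + 1 (log axis) of the genes of the sort markers in each mRNA library, with points for libraries and lines for the mean of each population. Cd4 is at 7.56 and 3.40 FPKM in DNT and at 478 and 499 in activated CD4, and Cd8a differs between the DNT libraries (4.74 and 112.7).

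The first comparison asked how DNT differed from activated cells that kept CD4. The largest rises included NK receptor genes. Klra7, of the Ly49 receptor family, was at 113 ± 29.8 FPKM in DNT and 5.11 ± 5.0 in activated CD4 (log2 change 4.49 ± 0.58, adjusted p = 0.00612). Klrd1, which encodes CD94, rose by 4.04 ± 0.39 (149 ± 48.2 against 8.58 ± 5.06 FPKM, adjusted p = 0.00313), and Klrk1, which encodes the activating receptor NKG2D, rose by 3.62 ± 0.38 (50.6 ± 0.81 against 3.25 ± 1.02, adjusted p = 0.00364). The largest falls included Il21 and Tnfrsf4. Il21, a helper T cell cytokine, stood at 0.715 ± 0.70 FPKM in DNT and 34.3 ± 1.27 in activated CD4 (−4.42 ± 0.30, adjusted p = 0.00154), and Tnfrsf4, which encodes OX40, at 26.6 ± 16.2 and 444 ± 40.3 (−4.15 ± 0.48, adjusted p = 0.00460).

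Of 12414 genes tested, 572 were higher and 922 lower in DNT than in activated CD4 (limma), against 636 and 835 with edgeR, and 1290 were called by both. At least 2-fold changes were seen in 373 of the higher and 606 of the lower genes. Leaving out 1 library gave 363 higher genes without DNT replicate 1, 238 without DNT replicate 2, 268 without activated CD4 replicate 1 and 346 without activated CD4 replicate 2. The lower genes then numbered 515, 410, 475 and 431. In simulated data of this comparison 200 of 11801 genes were changed, and limma called 51 of 65 changed by 2 (log2) and 6 of 64 changed by 1. More genes were called in the real data, which makes the adjustment less strict. The simulated shares therefore do not give the share of smaller changes missed here.

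The 15 largest rises ran from 3.53 to 4.49 on the log2 scale. Besides Klra7, Klrd1 and Klrk1 they were the NK receptor genes Klra5, Klre1, Klrc1, Klra1, Cd160 and Cd244a, the receptor adaptor gene Fcer1g (334 ± 9.66 FPKM against 29.3 ± 14.5), the granzyme gene Gzmc, and Ppp2r2c, Sult2b1, Spp1 and Car2. Spp1, which encodes osteopontin, reached 1576 ± 892 FPKM in DNT and 171 ± 190 in activated CD4 (3.76 ± 0.92, adjusted p = 0.0483), and its call ended with edgeR (0.0856) and without either DNT replicate, activated CD4 replicate 1 or either naive CD4 replicate (0.0540 to 0.180). Calls also ended for Ppp2r2c and Klra5 without DNT replicate 2 (0.0528 and 0.0568), for Gzmc without DNT replicate 2 or either naive CD4 replicate (0.0553 to 0.0864), and for Car2 with edgeR (0.0574) and without any of the DNT or activated CD4 replicates (0.0581 to 0.158). The 15 largest falls ran from −4.03 to −6.32. After Cd4 came Ly6c1 (4.51 ± 2.24 against 227 ± 11.4 FPKM, −5.43 ± 0.29), the enkephalin precursor Penk (12.2 ± 9.76 against 454 ± 96.7), and Ecm1 (79.7 ± 33.5 against 2913 ± 1297), followed by Adamtsl4, Nts, Akr1c18, Stra6, Il21, Ccr8, Cd24a, Tnfrsf4, Cd81, Izumo1r and Lgals7. The falls of Ccr8 and Cd24a were not called without activated CD4 replicate 1 (0.0691 and 0.0547), nor that of Ccr8 without activated CD4 replicate 2 (0.0743). Reads of the Klra genes, of Gzmc to Gzmg and of Ly6c1 and Ly6c2 can be shared between close copies, so the member is uncertain.

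**Figure D2:**
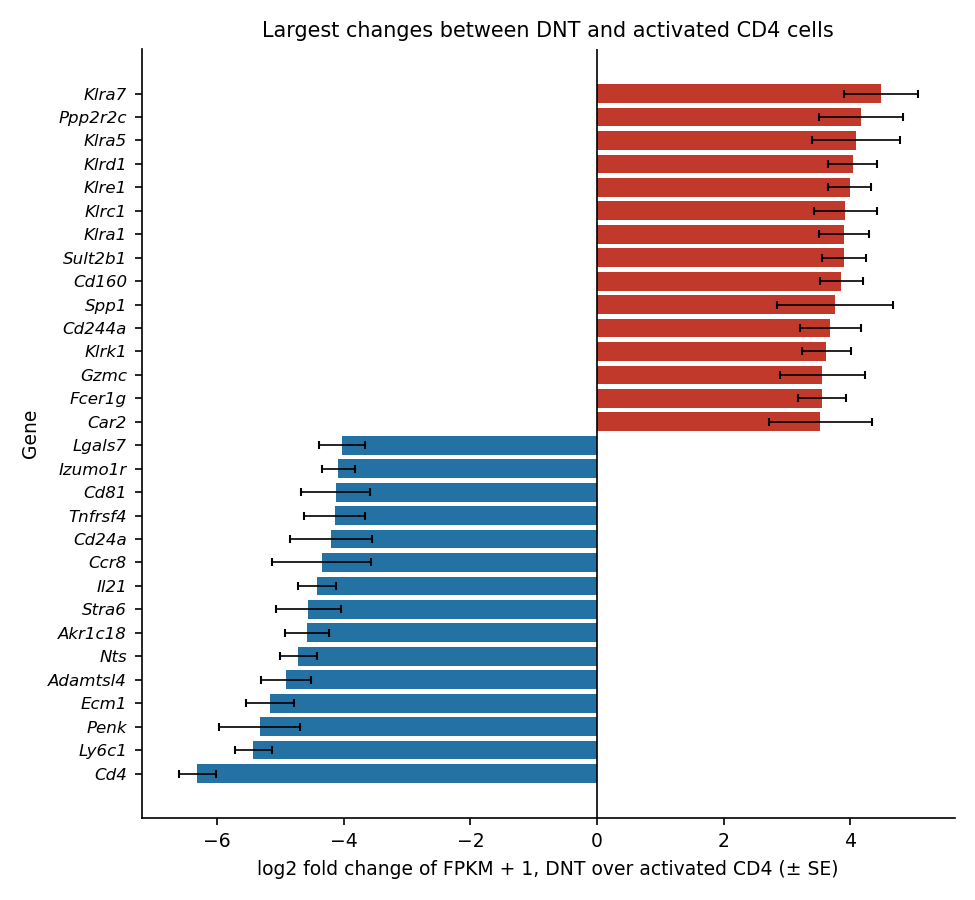
Log2 fold change of FPKM + 1, DNT over activated CD4, for the 15 largest rises and 15 largest falls, with bars for the fold change and lines for its SE (2 libraries per population). Rises reach 4.49 for Klra7 and falls reach −6.32 for Cd4.

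Of the 34 gene lists tested, camera with a preset correlation called 8 higher and 7 lower in DNT than in activated CD4. None held with an estimated correlation (0 calls by camera, 4 at an unadjusted p under 0.05), and fry called 8 lists, 6 of these 15 and 2 others. In the simulation an estimated correlation also called 0 of 5 lists raised by 0.5 (log2). A list lost with it is therefore not shown to be unchanged. The NK receptor, cytotoxic effector, CD8 T cell and γδ T cell lists were among those called higher. In the list of NK and NK receptor genes 13 of 16 rose (15 adjusted over the list alone), led by Klra7 and Klrd1 (camera adjusted p = 1.38e-15, adjusted p = 0.361 with an estimated correlation). Of 22 cytotoxic effectors 13 rose (16 adjusted over the list alone; adjusted p = 1.35e-13, adjusted p = 0.361 with an estimated correlation). Among these were Gzmc (1451 ± 631 FPKM against 150.2 ± 135), whose call ended without DNT replicate 2 or either naive CD4 replicate (0.0553 to 0.0864), and the granule membrane gene Nkg7 (849 against 81.7, 3.38 ± 0.20, adjusted p = 0.00131). Of 10 CD8 T cell genes 7 rose and 1 fell, also adjusted over the list alone, with Klrd1, Klrk1 and the transcription factor gene Eomes (96.1 against 10.2 FPKM, 3.12 ± 0.17) leading (adjusted p = 6.90e-07, adjusted p = 0.361 with an estimated correlation). The lists overlap, as Klrd1, Klrk1 and Cd7 are also in the NK receptor list and Eomes and Gzmk among the cytotoxic effectors. Of 8 genes of γδ and innate-like T cells 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00722, adjusted p = 0.420 with an estimated correlation). Those were the γ constant region genes Tcrg-C2 (344 against 22.5 FPKM), Tcrg-C4 (94.5 against 5.74) and Tcrg-C1 (89.6 against 11.2), which share sequence, and the transcription factor gene Maf (7.36 against 52.1). Beside these groups, T cell receptor δ segments, picked after their values were seen, summed to 33.2 FPKM in DNT replicate 1 and 416 in DNT replicate 2 (142 and 1114 reads on short segments, which inflate FPKM), to 13.2 and 28 in activated CD4 and to 53.2 and 54.4 in naive CD4.

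The cholesterol synthesis, unfolded protein response, ATF4 and oxidative phosphorylation lists were also called higher, with 8, 1, 2 and 0 members that rose. Of 22 cholesterol synthesis genes 8 rose (9 adjusted over the list alone; adjusted p = 1.31e-07, adjusted p = 0.585 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was at 96.3 against 32.8 FPKM (adjusted p = 0.00380), and Msmo1 rose by 1.08, a call lost without any of the DNT or activated CD4 replicates (0.0507 to 0.0579). In the unfolded protein response list 1 of 18 rose, Creld2 by 0.78 (camera adjusted p = 0.00243, adjusted p = 0.604 with an estimated correlation). With limma 0 passed when adjusted over the list alone, 6 were higher at an unadjusted p under 0.05, and edgeR called 2. Creld2 was not called without DNT replicate 1 or any activated or naive CD4 replicate (0.0533 to 0.157), nor was the list without DNT replicate 1 (0.148). Of 23 genes of the amino acid stress response through ATF4, Slc7a3 and Trib3 rose by 0.98 and 0.72 and Vldlr fell by 1.22, also adjusted over the list alone (adjusted p = 0.0233, adjusted p = 0.732 with an estimated correlation). The list was not called without DNT replicate 1 (0.0809) or activated CD4 replicate 2 (0.404), nor with quantile normalization (0.0647). Each of the 3 genes lost its call without activated CD4 replicate 1 or 2, Vldlr and Trib3 also without DNT replicate 1, Slc7a3 and Trib3 without DNT replicate 2 and Trib3 without either naive CD4 replicate (0.0509 to 0.240), and Vldlr with edgeR (0.108). The 29 oxidative phosphorylation genes were higher as a list (adjusted p = 0.0132, adjusted p = 0.746 with an estimated correlation), with 0 called by limma over all genes or adjusted over the list alone, 2 higher at an unadjusted p under 0.05 and 1 by edgeR. That call ended without DNT replicate 1 (0.176) or activated CD4 replicate 2 (0.744), and with quantile normalization (0.0705).

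The lineage regulator, co-stimulatory receptor, cytokine and naive gene lists were called lower. Of 16 CD4 and CD8 lineage regulators 8 fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.00501, adjusted p = 0.604 with an estimated correlation), among them Gata3, a factor of CD4 and type 2 helper cells (56.4 against 306 FPKM), and Satb1 (62.0 against 283 FPKM), which was not called without activated CD4 replicate 1 (0.0527). Of 14 co-stimulatory receptors 7 fell (8, and 2 that rose, adjusted over the list alone; adjusted p = 0.000384, adjusted p = 0.506 with an estimated correlation), led by Tnfrsf4 and Cd6 (5.07 against 74.1 FPKM). Of 20 cytokines 8 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.000721, adjusted p = 0.604 with an estimated correlation). Il21, Il9 (2.10 against 24.6 FPKM) and Il4 (10.9 against 93.7, −3.13 ± 0.39) fell, while Ifng, which encodes interferon γ, rose (176 against 21.3, 2.98 ± 0.22, adjusted p = 0.00188). Of 22 naive and quiescence genes 10 fell (13 adjusted over the list alone; adjusted p = 1.99e-06, adjusted p = 0.361 with an estimated correlation), Bach2 (2.47 against 21.8 FPKM) and Satb1 first. Satb1, Lef1 and Tcf7 are in this list and among the lineage regulators.

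Of 30 interferon-stimulated genes 7 fell (12, and 1 that rose, adjusted over the list alone; adjusted p = 0.000327, adjusted p = 0.732 with an estimated correlation). Oas2 fell by 1.98 and Ifi27l2a by 1.57, and both calls ended without DNT replicate 2 or either activated CD4 replicate, that of Ifi27l2a also without DNT replicate 1 (0.0524 to 0.146). Of 22 immediate early genes 8 fell (9, and 1 that rose, adjusted over the list alone; adjusted p = 0.00286, adjusted p = 0.585 with an estimated correlation), such as Nfkbia (121 against 485 FPKM) and Nr4a1 (2.41 against 11.4). Of 16 dendritic cell genes 4 fell (6, and 1 that rose, adjusted over the list alone; adjusted p = 0.00322, adjusted p = 0.604 with an estimated correlation), and the list was not called without DNT replicate 2 (0.171) or with no filter (0.102). These included H2-DMa (18.9 against 86.7 FPKM, adjusted p = 0.00244) and Cd83 (0.860 against 10), which was not called without DNT replicate 2 or either activated CD4 replicate (0.0697 to 0.111).

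**Figure D3:**
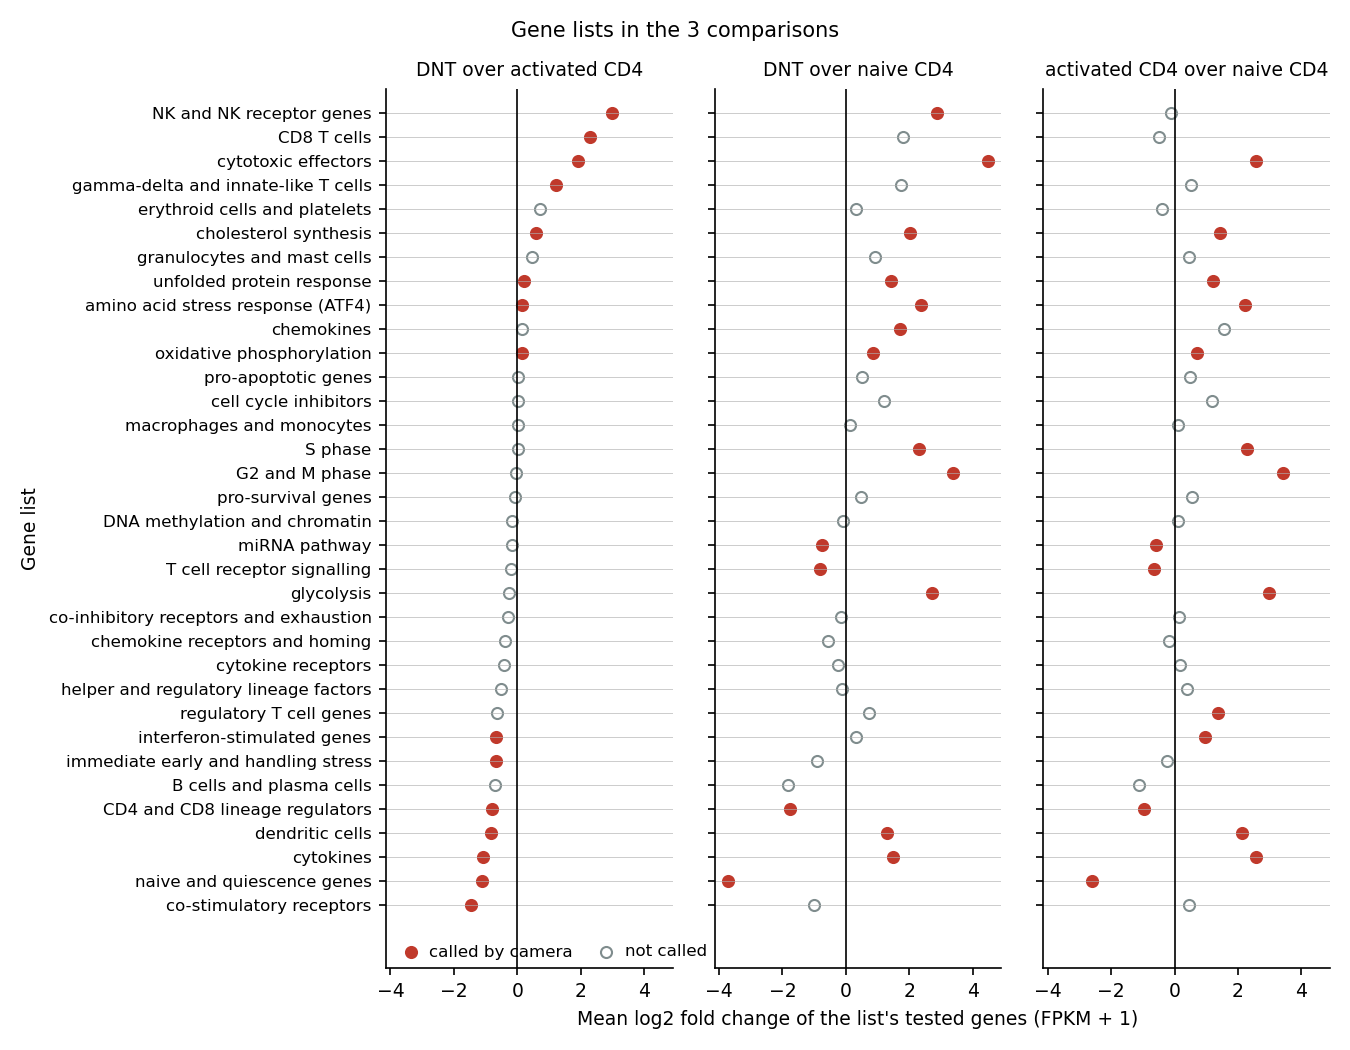
Mean log2 fold change of FPKM + 1 over the tested genes of each of 34 gene lists, in 3 panels for DNT over activated CD4, DNT over naive CD4 and activated over naive CD4. Filled points are lists called by camera with the preset correlation (15, 16 and 16), none of which was called with an estimated correlation.

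Other T cell lists were not called, though single genes changed. Of 18 regulatory T cell genes 2 rose and 5 fell (4 and 7 adjusted over the list alone; adjusted p = 0.157), such as Izumo1r (8.76 against 162 FPKM) and Ikzf2, which encodes Helios (64.3 against 7.34). Of 18 co-inhibitory receptor and exhaustion genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.470), with Cd5 at 2.81 against 57.8 FPKM and Cd160 at 62.4 against 3.38. Of 27 cytokine receptors 3 rose and 6 fell (5 and 11 adjusted over the list alone; adjusted p = 0.232), including Tgfbr3 (3.66 against 27.3 FPKM), Il7r (10.1 against 50.3) and Il18r1 (25.1 against 4.79). Of 21 chemokine receptor and homing genes 4 rose and 4 fell (5 and 6 adjusted over the list alone; adjusted p = 0.759), and the mean change of −0.39 and the upward direction of the test differ in sign. Ccr8 and Ccr4 fell (3.61 against 74.0 and 4.49 against 47.7 FPKM) and Ccr5 rose (340 against 65.8), Ccr8 not without either activated CD4 replicate (0.0691 and 0.0743). Of 10 chemokines 1 rose, also adjusted over the list alone (adjusted p = 0.572), Xcl1 by 2.79, a call lost without any DNT or activated CD4 replicate (0.0684 to 0.107). Of 21 helper and regulatory lineage factors 3 rose and 7 fell (3 and 9 adjusted over the list alone; adjusted p = 0.157, or 0.0256 without DNT replicate 1). Eomes led the rises and Irf4 the falls (9.70 against 64.2 FPKM), Irf4 not without activated CD4 replicate 1 (0.0541). Of 32 T cell receptor signalling genes 3 rose and 9 fell (6 and 10 adjusted over the list alone; adjusted p = 0.385), Themis by −2.19 and Ptpn22 by 1.38.

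Proliferation genes did not differ detectably. limma called 0 of 31 S phase genes (list adjusted p = 0.433) and 0 of 32 G2 and M phase genes (adjusted p = 0.840), over all genes and adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by edgeR. The S phase list was called without activated CD4 replicate 1 (0.0498), and in the G2 and M phase list the mean of −0.05 and the upward test differ in sign. Of 14 cell cycle inhibitors 3 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.841), with Cdkn2a at 29.5 against 5.62 FPKM and Cdkn2b at 10.5 against 1.70, the second not called by edgeR (0.0811). Of 17 pro-survival genes Pim2 rose by 1.01 and Birc3 fell by 0.75, also adjusted over the list alone (adjusted p = 0.759). Pim2 was not called without DNT replicate 1 (0.0518), nor Birc3 without DNT replicate 2 or either activated CD4 replicate (0.0703 to 0.132). Of 23 pro-apoptotic genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.525), Bcl2l11 by 2.05 and Fas by −1.70, with Bcl2l11 not called without any DNT or activated CD4 replicate (0.0510 to 0.0674). Of 18 glycolysis genes 3 fell, also adjusted over the list alone (adjusted p = 0.259), among them Pfkm and Hk2 by −1.13 and −0.99. Both lost their calls without DNT replicate 1 or either activated CD4 replicate, Hk2 also without DNT replicate 2 and with edgeR (0.0534 to 0.107). limma called 0 of 25 DNA methylation and chromatin genes (adjusted p = 0.328; 7 lower at an unadjusted p under 0.05, 1 by edgeR) and 0 of 17 miRNA pathway genes (adjusted p = 0.226; 3 lower at an unadjusted p under 0.05, 0 by edgeR), and 0 in each adjusted over the list alone.

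Markers of other cell types completed the lists. Of 5 B and plasma cell genes 2 fell (2, and 1 that rose, adjusted over the list alone; adjusted p = 0.313), Ighm from 22.8 in activated CD4 to 4.66 FPKM in DNT and Cd22 by −1.87, the second not without either DNT replicate, activated CD4 replicate 2 or either naive CD4 replicate (0.0582 to 0.0998). Of 13 macrophage and monocyte genes 1 rose, also adjusted over the list alone (adjusted p = 0.385), the lysosomal protease gene Ctsd (905 against 266 FPKM). limma called 0 of 9 granulocyte and mast cell genes, over all genes and adjusted over the list alone (adjusted p = 0.281; 2 higher at an unadjusted p under 0.05, 0 by edgeR), and called the list without activated CD4 replicate 1 (0.0102). Its genes differed between replicates. Cpa3 stood at 31.7 and 3.47 FPKM in DNT and 33.8 and 1.39 in activated CD4, and Mcpt8 at 12.6 and 5.09 and at 76.2 and 1.30, both chosen after their values were seen. Of 5 erythroid and platelet genes 1 rose, also adjusted over the list alone (adjusted p = 0.385), Car2 (90.7 against 7.72 FPKM), whose call ended with edgeR (0.0574) and without any DNT or activated CD4 replicate (0.0581 to 0.158). Of stroma and endothelium only Pecam1 was tested and rose by 1.17, a call lost without either DNT replicate, activated CD4 replicate 1 or either naive CD4 replicate (0.0826 to 0.168).

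The second comparison set DNT against naive CD4 cells. Gzma and Gzmb led the named rises. Gzma reached 14470 ± 2010 FPKM in DNT and 18.4 ± 6.42 in naive CD4 (log2 change 9.58 ± 0.34, adjusted p = 2.16e-05), and Gzmb reached 11000 ± 277 against 13.9 ± 0.49 (9.53 ± 0.15, adjusted p = 3.65e-06). Spp1, Gzmc, Gzmd, Gzmg, Ifitm1, Gzme, Lgals3 and AA467197, the transcript that holds miR-147, rose by 6.92 to 9.39. Falls included Tcf7, which encodes the factor TCF-1 (11 ± 0.52 against 868 ± 82.9 FPKM, −6.17 ± 0.29, adjusted p = 3.65e-05) and Dtx1 (0.570 ± 0.37 against 199.8 ± 4.01, −7.02 ± 0.21, adjusted p = 2.16e-05). Cd4, Il6ra, Vipr1, Dapl1, S1pr1, Cd5, Nsg2 and Cmah had log2 changes of −5.89 to −6.79. In all 3533 genes were higher and 4083 lower (limma), against 3954 and 3686 with edgeR, and 7150 were called by both. The median change of all genes was −0.10, and −0.20 with FPKM rescaled to equal sums.

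The third comparison set activated CD4 against naive CD4 cells. The largest rises included Lama5, Il13 and Gzmb. Il13 was at 210.3 ± 15.6 FPKM against 0.390 ± 0.26 (7.26 ± 0.63, adjusted p = 0.000282), Lama5, a laminin chain gene, at 314 ± 173 against 0.423 ± 0.035 (7.67 ± 0.37, adjusted p = 6.59e-05), and Gzmb at 1562 ± 300 against 13.9 ± 0.49 (6.70 ± 0.15, adjusted p = 1.75e-05). Cyp11a1, Gzma, Il24, Penk, Tgm2, Lif and Gzmg rose by 6.59 to 7.59. Dtx1, Dapl1, Vipr1, Il6ra, Cmah, Nsg2, St8sia6, Tcf7 and Slc16a5 had log2 changes of −4.60 to −6.44. The mitochondrial ribosomal RNA gene mt-Rnr2 also fell (13.4 ± 6.22 against 469 ± 94.7 FPKM, adjusted p = 0.0426), not without either activated or either naive CD4 replicate (0.0887 to 0.162). In all 3403 genes were higher and 3449 lower (limma), against 3623 and 3281 with edgeR, and 6531 were called by both. The median change of all genes was −0.04, and −0.14 with FPKM rescaled to equal sums.

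Camera called 12 lists higher and 4 lower than naive CD4 in each of these comparisons (fry called 25 and 23 lists), and none with an estimated correlation (0 calls by camera, 2 at an unadjusted p under 0.05 in each). Since that setting called 0 of 5 raised lists in the simulation, its adjusted p-values below do not show that a list is unchanged. The S phase and G2 and M phase lists were higher in both DNT and activated CD4. In DNT 30 of 31 S phase genes rose (31 adjusted over the list alone; adjusted p = 2.03e-12, adjusted p = 0.457 with an estimated correlation) and in activated CD4 all 31, also adjusted over the list alone (adjusted p = 5.64e-13, adjusted p = 0.436 with an estimated correlation). Rrm2 stood at 296 FPKM in DNT, 268 in activated CD4 and 13.2 in naive CD4. Of 32 G2 and M phase genes 31 rose in each, also adjusted over the list alone (adjusted p = 7.58e-14 and 1.46e-14, adjusted p = 0.457 and 0.436 with an estimated correlation), with Cdk1 at 125, 129 and 5.39 FPKM. Cytotoxic effectors rose in 20 of 22 genes in DNT and 16 in activated CD4, also adjusted over the list alone (adjusted p = 3.70e-10 and 2.59e-05, adjusted p = 0.457 and 0.436 with an estimated correlation), Gzma and Gzmb first in both. The NK and NK receptor list was called in DNT, with 14 of 16 genes higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 4.77e-05, adjusted p = 0.457 with an estimated correlation), led by Fcer1g (334 against 7.01 FPKM) and Klra7 (113 against 1.82). It was not called in activated CD4 (adjusted p = 0.868), where 3 rose and 2 fell (1 and 1 adjusted over the list alone).

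The glycolysis, oxidative phosphorylation, cholesterol synthesis, ATF4 response and unfolded protein response lists were higher in both. Of 18 glycolysis genes 17 rose in DNT (17, and 1 that fell, adjusted over the list alone) and 18 in activated CD4, also adjusted over the list alone (adjusted p = 3.58e-09 and 7.26e-11, adjusted p = 0.325 and 0.248 with an estimated correlation). Slc16a3 stood at 238 FPKM in DNT and 264.5 in activated CD4 against 3.91 in naive CD4, and Hk2 at 95.8 and 191.0 against 2.10. Of 29 oxidative phosphorylation genes 22 and 21 rose (23 and 22 adjusted over the list alone; adjusted p = 1.98e-06 and 2.83e-05, adjusted p = 0.524 and 0.678 with an estimated correlation), with Cycs up by 2.62 and 2.36. Of 22 cholesterol synthesis genes 21 and 19 rose, also adjusted over the list alone (adjusted p = 6.00e-09 and 3.88e-07, adjusted p = 0.457 and 0.436 with an estimated correlation), Fdps by 3.40 and 2.58. Of 23 ATF4 response genes 22 rose in each, also adjusted over the list alone (adjusted p = 6.43e-09 and 9.11e-09, adjusted p = 0.457 and 0.436 with an estimated correlation), with Asns, which makes asparagine, at 272 and 162 against 2.39 FPKM. Of 18 unfolded protein response genes 16 rose and 1 fell in DNT, also adjusted over the list alone, and 15 and 1 in activated CD4 (15 and 2 adjusted over the list alone; adjusted p = 2.18e-06 and 2.85e-05, adjusted p = 0.457 and 0.436 with an estimated correlation), Sdf2l1 by 3.71 and 3.43. The immediate early list was not called, with 3 of 22 genes that rose and 10 that fell in DNT (adjusted p = 0.0722) and 6 and 9 in activated CD4 (adjusted p = 0.429), also adjusted over the list alone. In DNT it was called lower without DNT replicate 2 (0.0413) or naive CD4 replicate 1 (0.00403), with no filter (0.0333) and with quantile normalization (0.0450).

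The naive and quiescence, lineage regulator, T cell receptor signalling and miRNA pathway lists were lower in both. All 22 naive and quiescence genes fell in DNT, also adjusted over the list alone, and 19 in activated CD4 (20 adjusted over the list alone; adjusted p = 4.79e-09 and 2.17e-07, adjusted p = 0.375 and 0.436 with an estimated correlation), Il6ra by −6.51 and −5.64 and Dapl1 by −6.27 and −5.77. Of 16 lineage regulators 12 fell and 2 rose in DNT (13 and 2 adjusted over the list alone) and 10 fell and 2 rose in activated CD4 (10 and 3 adjusted over the list alone; adjusted p = 0.00111 and 0.0210, adjusted p = 0.457 and 0.678 with an estimated correlation). Tcf7 and Tox led in both, and Gata3 rose in activated CD4 (306 against 88.9 FPKM, adjusted p = 0.00375). Of 32 T cell receptor signalling genes 23 fell and 1 rose in DNT (24 and 1 adjusted over the list alone) and 20 fell and 2 rose in activated CD4 (21 and 2 adjusted over the list alone; adjusted p = 0.000146 and 0.000424, adjusted p = 0.457 and 0.436 with an estimated correlation), with Dgka at 43.0 and 82.4 against 628 FPKM. Of 17 miRNA pathway genes 11 fell and 1 rose in DNT and 10 fell and 2 rose in activated CD4, also adjusted over the list alone (adjusted p = 0.0132 and 0.0210, adjusted p = 0.457 and 0.436 with an estimated correlation), Tnrc6b by −2.14 and −1.80.

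The cytokine list and the list of dendritic cell markers were higher in both, and the chemokine list in DNT. Of 20 cytokines 12 rose and 2 fell in DNT, also adjusted over the list alone, and 14 rose and 1 fell in activated CD4 (16 and 1 adjusted over the list alone; adjusted p = 0.0157 and 2.83e-05, adjusted p = 0.524 and 0.436 with an estimated correlation), and the DNT call ended without naive CD4 replicate 1 (0.0543). Il24 rose by 5.45 and 7.05 and Il13 by 4.76 and 7.26, and Il9, at 24.6 FPKM in activated CD4, is listed at 0 in both naive CD4 libraries. Of 10 chemokines 6 rose in DNT, also adjusted over the list alone (adjusted p = 0.0265, adjusted p = 0.457 with an estimated correlation, 0.134 without naive CD4 replicate 1 and 0.0766 with the filter at FPKM 5), Ccl22 by 4.30. In activated CD4 7 chemokines rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0655), and the list was called without either DNT replicate, activated CD4 replicate 2 or naive CD4 replicate 2 (0.0188 to 0.0485) and with no filter or rescaling to TPM (0.0316 and 0.0389). Of 16 dendritic cell genes 9 rose and 1 fell in DNT, also adjusted over the list alone, and 11 rose in activated CD4 (12 adjusted over the list alone; adjusted p = 0.0191 and 0.000144, adjusted p = 0.524 and 0.436 with an estimated correlation), the DNT call ending without DNT replicate 1 or naive CD4 replicate 1 (0.0744 and 0.0739). Batf3, also a factor of activated T cells, rose by 5.25 and 5.65, and Ccl22 stood at 40.1 and 11.2 FPKM in the DNT libraries and 107.8 and 30 in those of activated CD4. In activated CD4 alone the interferon-stimulated list was called, with 15 of 30 genes higher and 1 lower, also adjusted over the list alone (adjusted p = 0.00137, adjusted p = 0.704 with an estimated correlation and 0.0833 with fry), Ly6a by 4.04 and Isg20 by 2.88. So was the regulatory T cell list, with 9 of 18 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.0364, adjusted p = 0.678 with an estimated correlation), not without activated CD4 replicate 1 (0.0595) or naive CD4 replicate 1 (0.237), nor with median-of-ratios or trimmed mean scaling (0.0601 and 0.0580). In DNT these lists had adjusted p = 0.308 (0.0457 without naive CD4 replicate 1) and 0.0826 (0.0103 without naive CD4 replicate 2, 0.0280 with no filter and 0.0320 with the filter at FPKM 5). The populations are compared directly for these lists by the test of DNT against activated CD4 above. There camera called the interferon-stimulated list lower in DNT (adjusted p = 0.000327, 0.732 with an estimated correlation and 0.164 with fry). It did not call the regulatory T cell or chemokine list (camera adjusted p = 0.157 and 0.572).

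Both comparisons share the naive CD4 libraries. Of the genes tested, 2830 were higher and 3050 lower in both DNT and activated CD4. Simulated groups without change, sharing 2 naive libraries drawn around the naive CD4 means, gave 0.01 and 0.06 genes on average in 100 draws. Few genes are called where nothing changes, so these overlaps were near 0 by construction. Independent lists of the observed sizes would overlap in 968 and 1134 genes. The log2 changes correlated at r = 0.877 across genes, which are not independent replicates (simulated 0.501), with a covariance of 1.497 (simulated 0.03, a difference of 1.47). Splitting the naive libraries would leave 1 for each comparison, so they were not split. Part of the excess of the overlaps over independent lists may come from the shared controls. The simulated correlation and covariance already include the sharing of 2 naive libraries, though only for the spread between libraries. DNT was higher than both CD4 populations in 435 genes and lower than both in 549 (462 and 529 with edgeR), among them Gzmb and Nkg7 on the higher side and Cd4, Cd5 and Ly6c1 on the lower. The higher genes numbered 265 without DNT replicate 1, 191 without DNT replicate 2 and 215 without activated CD4 replicate 1. The lower genes numbered 292, 240 and 270 without these, and 269 without activated CD4 replicate 2.

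Small RNA libraries held 5017781 reads in DNT, 3938307 in activated CD4 and 4666611 in naive CD4, 1 library each, so the values below compare these libraries, with no replicate check. miR-21a-5p, which rises in activated T cells, took 69.5% of the miRNA reads in DNT, 48.1% in activated CD4 and 23.0% in naive CD4. Next in DNT came let-7i-5p (4.04%), let-7f-5p (2.43%), miR-27b-3p, let-7g-5p, miR-7a-5p, miR-142a-5p, miR-142a-3p with miR-142b, and miR-20a-5p (0.842%). Activated CD4 had let-7g-5p (5.90%) second, with miR-155-5p (2.54%), miR-29a-3p (1.60%) and miR-146a-5p (1.23%) in its first 10, and naive CD4 had let-7g-5p (10.9%), miR-150-5p (6.88%) and miR-30d-5p (3.93%). miR-142a-3p and miR-142b have equal counts in DNT and in naive CD4, so each value is uncertain.

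Of 254 miRNAs compared between DNT and activated CD4, 11 were at least 2-fold higher and 103 at least 2-fold lower in DNT. With median-of-ratios scaling the split was 32 and 71, and the median log2 ratio moved from −0.715 to 0.014. With miR-21a-5p left out of the totals, a setting chosen after seeing the data, the split was 33 and 70. Members of the miR-106a~363 cluster, a paralogue of miR-17~92, led the higher side, with miR-18b-5p at 3.78 times (95% interval 3.37 to 4.26, counting error only), miR-106a-5p at 3.66, miR-20b-5p at 3.08 and miR-363-3p at 2.51, before miR-139-5p, miR-130b-5p and miR-149-5p. On the lower side, activated CD4 exceeded DNT by 40 times for miR-9-5p (34.8 to 46.2) and 15.6 times for miR-155-5p, a miRNA of activated lymphocytes (15.3 to 16, 8156 against 100141 reads). miR-99b-5p, miR-10a-5p, miR-146b-5p, miR-34a-5p, miR-669a-3p and miR-29a-3p were lower by 8.63 to 22 times. With median-of-ratios scaling all 15 of these log2 ratios shifted up, that of miR-18b-5p from 1.92 to 2.65 and that of miR-155-5p from −3.97 to −3.24.

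**Figure D4:**
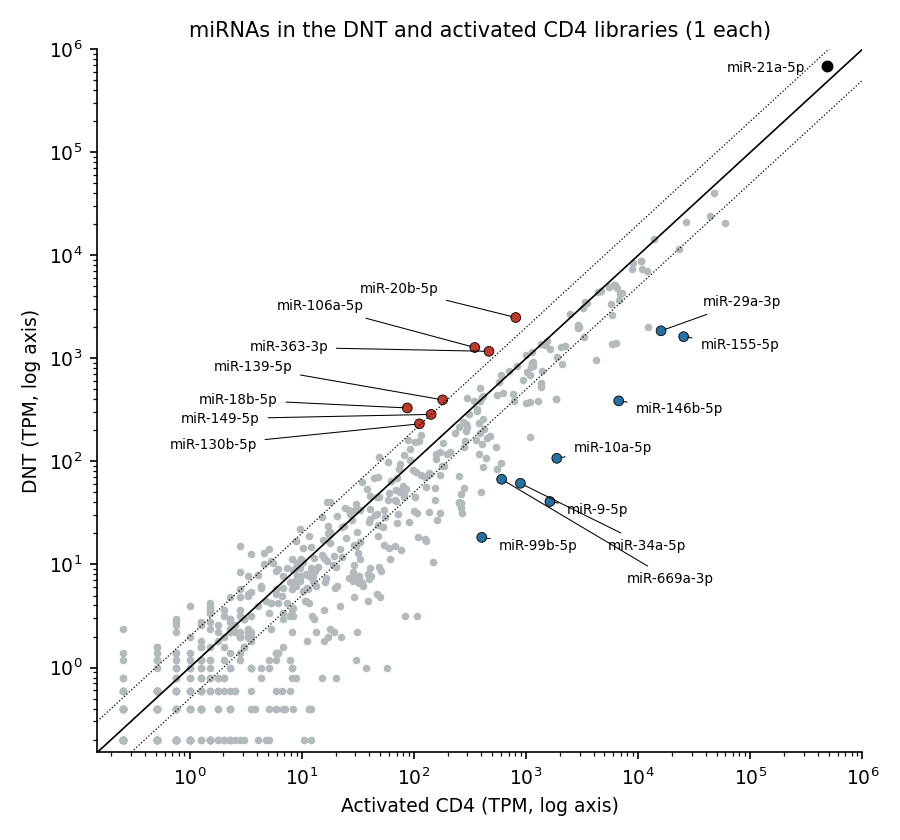
TPM of each miRNA in DNT (vertical) against activated CD4 (horizontal), both on log axes, 1 library each, with the solid line at equality and dotted lines at 2-fold. Red and blue points are the named higher and lower miRNAs, from 3.78 times for miR-18b-5p to 40 times lower for miR-9-5p, and the black point is miR-21a-5p at 69.5% and 48.1% of reads.

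Against naive CD4, 63 miRNAs were higher and 120 lower in DNT (of 261), and 83 were higher and 56 lower in activated CD4 (of 263, or 66 and 81 with median-of-ratios and 70 and 77 with trimmed mean scaling). With miR-21a-5p left out of the totals (chosen after seeing the data) the split turned to 116 higher and 66 lower in DNT, and was 104 and 21 in activated CD4. miR-147-3p was 263 times higher in DNT (173.5 to 420) and 346 times higher in activated CD4 (228 to 552), and miR-210-3p, induced by low oxygen, 63.8 and 151 times. miR-18b-5p, miR-222-3p, miR-183-5p, miR-221-3p, miR-182-5p and miR-96-5p also led in DNT. Activated CD4 had miR-147-5p (679 times, 187.5 to 5613, from 2 reads in naive CD4), miR-34a-5p (119 times), miR-9-5p, miR-10b-5p, miR-146b-5p and miR-212-5p. Naive CD4 exceeded DNT by 65.5 times for miR-181a-5p and 48.5 times for miR-150-5p, miRNAs of developing and resting lymphocytes, and exceeded activated CD4 by 10.5 and 10.9 times. let-7b-5p and let-7c-5p fell from naive CD4 by 23.9 and 21.4 times in DNT and 6.15 and 6.52 times in activated CD4.

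By miRNA list, members of the miR-17~92 and paralogous clusters were 2-fold higher in 5 of 18 cases in DNT against activated CD4, with the list median of −0.09 (log2) at percentile 99.5 of 10000 random lists. The 5 were miR-106a-5p, miR-18b-5p, miR-20b-5p, miR-363-3p and miR-363-5p, all of the miR-106a~363 cluster, while miR-17-5p stood at 0.949, miR-92a-3p at 0.688 and miR-19b-3p at 0.536 times the activated CD4 level. Activation-linked miRNAs were 2-fold lower in 8 of 13 (percentile 1.0), myeloid and dendritic cell miRNAs in 5 of 6 (0.2), and the miR-10 and miR-99 families in 3 of 3 (0.7). The other medians stood at percentile 28.8 for let-7 (4 of 12 lower), 40.9 for miR-181 (2 of 6 lower) and 16.4 for miR-29 (3 of 5 lower, 1 higher). Percentiles were 86.2 for miR-15 and miR-16, 45.2 for miR-30 (1 of 8 lower) and 96.5 for the miR-23, miR-27 and miR-24 clusters (1 of 9 lower). The miR-183 cluster was at 89.7, miR-221 and miR-222 at 95.2 and miR-34 and miR-449 at 96.7 (1 of 3 lower). Naive-linked miRNAs were at 8.2 (6 of 13 lower, 2 higher). Erythroid and Dlk1-Dio3 miRNAs had 0 members with enough reads. Against naive CD4, activation-linked miRNAs were higher in 12 of 13 in activated CD4 and 7 of 12 in DNT (percentiles 100 and 99.3), and the miR-30 family was lower in 8 of 8 in each.

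The listed targets of these miRNAs were read from the mRNA test. These targets were listed from general knowledge before the data were examined, with no search for seed sites. For miR-155-5p, at 0.0639 times the activated CD4 level in DNT, 2 of 9 tested targets changed, Maf by −2.65 and Ikbke by −1.05, in the direction of the miRNA. Bach1, with a log2 change of 0.79 against the miRNA (adjusted p = 0.0513), was called with edgeR (0.0473) and without either naive CD4 replicate (0.0466 and 0.0482), and Socs1, at −0.92, without activated CD4 replicate 1 (0.0232). For the miR-29 family, at 0.121 times, 2 of 9 changed and both rose (Eomes and Ifng). Changed targets that moved against their miRNA numbered 0 of 2 for miR-146a-5p, 0 of 1 for miR-150-5p, 1 of 2 for miR-181a-5p, 2 of 4 for let-7, 2 of 4 for miR-21a-5p, 2 of 2 for miR-17~92, 0 of 2 for miR-15 and miR-16, 1 of 2 for miR-125, 0 of 2 for miR-27 and 1 of 3 for miR-24. With median-of-ratios scaling, or with miR-21a-5p left out of the totals, small ratios turned and these became 0 of 2 for miR-17~92, 2 of 2 for miR-15 and miR-16, 2 of 2 for miR-27 and 2 of 3 for miR-24. Among the changed targets, Pten, Bcl2l11, Ccnd2, Pdcd4, Relb and Hk2 were not called without any 1 of the DNT or activated CD4 replicates (0.0510 to 0.174), nor Ccnd3 without any 1 library (0.0779 to 0.261). Calls also ended for Myc, S1pr1 and Tiam1 without DNT replicate 2 or either activated CD4 replicate, for Tiam1 without either naive CD4 replicate (0.0509 to 0.141), for Tcf7 without either DNT or either naive CD4 replicate (0.0509 to 0.0694) and for Egr2 without activated CD4 replicate 2 (0.0555). edgeR did not call Ccnd3, Hk2, Relb or Tiam1 (0.0514 to 0.0863). Calls were gained by Tet1 with edgeR (0.0225), E2f2 without either naive CD4 replicate (0.0355 and 0.0362), Myb without DNT replicate 1 (0.0283) and Tgfbr2 without activated CD4 replicate 2 (0.0359). No tested target of miR-182-5p, miR-10a-5p, miR-34a-5p or miR-31-5p was called. Over all 16 miRNAs and miRNA groups, 11 of 28 changed pairs moved against the miRNA in DNT against activated CD4. With median-of-ratios scaling, or with miR-21a-5p left out, this was 14 of 28. Against naive CD4, over all 16 miRNAs and miRNA groups, 44 of 68 changed miRNA and target pairs moved against the miRNA in DNT and 44 of 68 in activated CD4 (of 93 tested). With miR-21a-5p left out of the totals these were 43 and 35, and pairs share genes, so the numbers carry no test.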

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

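Depth and sample number limit what these libraries can show. In simulated data of DNT against activated CD4, 200 of 11801 genes were changed. There limma called 6 of 64 genes changed by 1 (log2) and 51 of 65 changed by 2. In the real data more genes were called, and 373 of 572 higher and 606 of 922 lower ones changed at least 2-fold. The adjustment is then less strict, so the share of smaller changes missed is not known. A miRNA with 0 reads may stand at up to 0.598 to 0.762 TPM. With 2 libraries per population, leaving 1 out leaves a lone sample that is assumed to vary like the other groups. Each setting below changed 1 choice, except edgeR, which changes the values, their scaling and the test, and 0 of the genes named by rule, the gene lists and the 47 named miRNA ratios reversed under any of them. Smaller miRNA ratios did turn with median-of-ratios scaling, such as let-7i-5p (log2 −0.24 to 0.49) and miR-20a-5p (−0.09 to 0.64) in DNT against activated CD4. The search for miRNA seed sites and its 8mer version were not run, and the filter at a mean FPKM of 5 leaves 32 of the 34 lists. For values that changed, the cause was not tested unless stated.

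Counts of genes in DNT against activated CD4 (572 higher, 922 lower) were 380 and 559 with no filter, which adds genes to the adjustment, and 223 and 343 at an adjusted p under 0.01. At least 2-fold left 373 and 606, fewer by construction. Left-out libraries gave 238 to 505 higher and 410 to 840 lower, with fewer samples in the fit. At least 2-fold left 2084 of 3533 higher and 2266 of 4083 lower in DNT against naive CD4, and 2054 of 3403 and 1759 of 3449 in activated against naive CD4, where an adjusted p under 0.01 left 2208 lower. Genes higher than both CD4 populations in DNT (435) numbered 174 at an adjusted p under 0.01, 278 at 2-fold or more and 191 to 372 with 1 library left out. Those lower than both (549) numbered 197, 285 and 240 to 487, and 266 with no filter. The covariance of the changes from naive (1.497) was 2.415 at a pseudocount of 0.1, which widens the changes of low genes. Under the other settings, edgeR (chosen after seeing the data) among them, these counts of genes stayed within 1.5 times.

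The labels do not say whether the replicate numbers pair the libraries. Replicate 1 minus replicate 2 correlated across genes at r = 0.407 (DNT and activated), 0.049 (DNT and naive) and 0.201 (activated and naive). A pairing of the DNT with the activated CD4 replicates of the same number therefore stays open. With the number as a replicate block, counts were 705 higher and 1141 lower in DNT against activated CD4, 3821 and 4403 in DNT against naive CD4, and 3758 and 3757 in activated against naive CD4. DNT was then higher than both in 541 and lower than both in 703. These are within 1.5 times of the counts without it, and no list call changed. Among named genes, the block ended 5 calls (Car2, Fasl, Hmgcr, Pecam1 and Trib3) and added 11 in DNT against activated CD4, ended that of Cd3e and added 6 in DNT against naive CD4, and ended that of Myb and added 4 in activated against naive CD4.

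With an estimated correlation camera called 0 of 5 raised lists in the simulation, so a loss under it cannot tell changed from unchanged lists. All 15 lists called by camera in DNT against activated CD4 were lost with an estimated correlation. Adjusted p was then 0.361 for cytotoxic effectors, naive and quiescence genes, NK and NK receptor genes and CD8 T cells, 0.420 for γδ and innate-like T cells, 0.506 for co-stimulatory receptors, and 0.585 for cholesterol synthesis and immediate early genes. It was 0.604 for lineage regulators, cytokines, the unfolded protein response and dendritic cells, 0.732 for interferon-stimulated genes and the ATF4 response, and 0.746 for oxidative phosphorylation. Lists lost with fry were lineage regulators and cytokines (0.0526 each), immediate early genes (0.0534), dendritic cells (0.0639), cholesterol synthesis (0.0661), interferon-stimulated genes (0.164), the unfolded protein response (0.182), the ATF4 response (0.460) and oxidative phosphorylation (0.675). fry gained B and plasma cells (0.0272) and DNA methylation and chromatin (0.0387). Against naive CD4, fry gained 9 lists in DNT and lost 0, and in activated CD4 gained 8 and lost interferon-stimulated genes (0.0833). Quantile normalization lost oxidative phosphorylation (0.0705) and the ATF4 response (0.0647), no filter lost dendritic cells (0.102), and the filter at FPKM 5 gained helper and regulatory lineage factors (0.0385). With 1 library left out, adjusted p ranged from 0.0498 to 0.781 for S phase, 0.000558 to 0.404 for the ATF4 response, 1.26e-05 to 0.171 for dendritic cells, 0.0102 to 0.939 for granulocytes and mast cells, 0.0256 to 0.285 for helper and regulatory lineage factors, 1.76e-05 to 0.744 for oxidative phosphorylation and 2.00e-05 to 0.148 for the unfolded protein response.

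Of 187 named genes in DNT against activated CD4, 172 kept their side of the threshold with edgeR (13 weaker, 2 stronger) and 146 with no filter (41 weaker), and 13 to 39 were lost with 1 library left out. Of 212 in DNT against naive CD4, edgeR kept 207 and left-out libraries lost 3 to 16. Of 204 in activated against naive CD4, edgeR kept 198 and left-out libraries lost 2 to 15.

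Of the miRNAs in DNT against activated CD4 (11 higher, 103 lower), 32 were higher with median-of-ratios and 17 with trimmed mean scaling, 23 at a minimum of 20 reads, 7 at 1000 reads and 18 at a ratio of 1.5, and 162 were lower at 20 reads and 46 at 1000. With miR-21a-5p left out of the totals (chosen after seeing the data) 33 were higher in DNT against activated CD4, 116 higher and 66 lower in DNT against naive CD4, and 21 lower in activated against naive CD4. In DNT against naive CD4 (63 and 120), 104 were higher at 20 reads and 24 at 1000, and 65 lower at 1000. In activated against naive CD4 (83 and 56), 132 were higher at 20 reads and 35 at 1000, and 89 were lower at a ratio of 1.5. Minimums and ratios change these counts by construction, as they admit more or fewer miRNAs. Of the named miRNA ratios, median-of-ratios and trimmed mean scaling each moved 15 of 15 beyond the counting interval in DNT against activated CD4, 14 and 8 of 16 in DNT against naive CD4, and 10 and 8 of 16 in activated against naive CD4.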

Other observations

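Every explanation test below was chosen only after its result was seen, except the host gene correlations, whose predictions were written before they were computed but after the miRNA ratios and some host gene values had been seen.

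Some genes moved in opposite directions from naive CD4 in DNT and in activated CD4. Of 12414 genes tested, 38 were lower in DNT and higher in activated CD4, and 21 were higher in DNT and lower in activated CD4. The first count was 19 without DNT replicate 2, 18 without naive CD4 replicate 1 and 20 without naive CD4 replicate 2. The second was 13 without DNT replicate 2, 8 without activated CD4 replicate 1, 8 without naive CD4 replicate 1 and 10 without naive CD4 replicate 2. The genes named here were chosen after their values were seen. Ly6c1 stood at 4.51 FPKM in DNT, 227 in activated CD4 and 107 in naive CD4 (log2 change from naive −4.33 in DNT and 1.1 in activated CD4), though its activated CD4 call ended without either activated CD4 replicate or naive CD4 replicate 2 (0.0568 to 0.108). Themis, a gene of T cell receptor signalling, stood at 22.5, 106 and 45.7 FPKM (−1.0 and 1.20), and Cd200, which encodes an inhibitory ligand, changed by −1.88 and 1.71. Ikzf2, which encodes Helios, stood at 64.3, 7.34 and 33.7 FPKM (0.96 and −2.04), with the DNT call lost without either DNT replicate or naive CD4 replicate 1 (0.0654 to 0.0962). Baiap3 stood at 21.7, 1.35 and 6.25 FPKM (1.66 and −1.66).

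Genes of other cell types, also chosen after their values were seen, differed between populations or between replicates. Ly6g stood at 55.6 and 53.7 FPKM in DNT and 0.0673 and 0.197 in naive CD4, and at 31.9 and 7.38 in activated CD4. Mpo was at 32 and 0.290 FPKM and Prg2 at 6.36 and 0.25 in the naive CD4 libraries, while Jchain was at 0.740 and 10.7 and C1qa at 0.207 and 12.3.

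The rise of NK receptor genes in DNT was set against other cells in the gate. NK cells would bring genes restricted to them, yet the highest DNT mean of Ncr1, Klra8, Klra4 and Klrb1f was 1.35 FPKM (means of 0.0822 to 0.362 in activated CD4 and 0.610 to 1.21 in naive CD4), while the 13 called list members had a median of 42.9 FPKM in DNT and 3.996 in naive CD4, so NK cells are unlikely to account for the rise. An excess of γδ T cells in DNT replicate 2 would raise the list there with the δ segments (log2 ratio 3.65), but the median log2 ratio of replicate 2 to replicate 1 over the called members was −0.148, with 8 of 13 lower. γδ T cells in both DNT libraries stay open as a source. In DNT replicate 1 the δ segments summed to 0.617 times the naive CD4 level. The γ constant regions Tcrg-C1, Tcrg-C2 and Tcrg-C4 stood at 18.7 times their naive CD4 level there (median). Against activated CD4 (13.2 and 28 FPKM) the δ sum of DNT replicate 1 was higher, at 33.2 FPKM. Conversion of CD4 cells, which the design offers as the biological explanation, was not tested by these values.

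Cd8a was at 112.7 FPKM in DNT replicate 2 and 4.74 in replicate 1. γδ T cells, some of which carry CD8α alone, may account for it, as the summed T cell receptor δ segments were 12.55 times higher in replicate 2 (33.2 and 416 FPKM) and 6 of 6 segments with reads were higher, although γδ cells were selected against at the start and CD8+ cells at the sort. Short segments inflate FPKM (Trdj1 gave 288 FPKM from 405 reads), so the sum is no level to set beside Cd8a (9677 reads). The δ constant region is not listed in the file. The γ constant regions Tcrg-C1, Tcrg-C2 and Tcrg-C4 had smaller log2 ratios of replicate 2 to replicate 1 (0.929, 0.524 and 1.111) than Cd8a (4.309). Those of the α and β constant regions Trac, Trbc1 and Trbc2 were −0.193, −0.119 and −0.266. CD8αβ T cells would bring Cd8b1, which was at 0.460 FPKM in replicate 2, and dendritic cells with Cd8a would bring H2-Aa, H2-Ab1, H2-Eb1 and Cd74, whose median log2 ratio was −1.598, so these tests speak against both. No biological explanation was tested, since the design gives no difference between the replicates.

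More miRNAs were lower than higher in DNT against activated CD4 (103 and 11), and miR-21a-5p took 69.5% and 48.1% of the reads. Without miR-21a-5p in the library totals the median log2 ratio was 0.049 in place of −0.715, so its reads may account for the shift of the median. More miRNAs were still lower (70) than higher (33). Against naive CD4 the same step moved the median away from 0 in activated CD4 (0.019 to 0.589) and past it in DNT (−0.713 to 0.62). A difference between the populations themselves cannot be told from a difference between single libraries here.

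A hypothesis was that miRNAs change with the genes that hold them. Host genes were taken from general knowledge, not from gene positions. Across 35 pairs of miRNA and host gene, the Spearman correlation of log2 changes was 0.623 in DNT against activated CD4, 0.644 in DNT against naive CD4 and 0.566 in activated against naive CD4 (permutation test, adjusted p = 0.00015, 9e-05 and 0.0005, adjusted over the 3 comparisons). Without the 2 pairs farthest out it was 0.55, 0.584 and 0.483. Where a called host gene rose (or fell), the miRNA ratio lay above (or below) the pairs' median in 6 of 6, 20 of 25 and 19 of 26 cases. This is not the same direction of change. In DNT against activated CD4 the count includes AA467197, which rose by 0.88, with miR-147-3p at a log2 ratio of −0.395. These values are consistent with shared transcription of host and miRNA, though pairs are not independent replicates, each miRNA value rests on 1 library per population and the comparisons share libraries. In DNT against activated CD4, Mir155hg changed by −1.79 and miR-155-5p by −3.97, while the host of miR-21a-5p, Vmp1, changed by −0.05 and the miRNA by 0.53. The reads of miR-21a-5p are a large part of its own library totals. With median-of-ratios scaling its log2 ratio was 1.257, and with its reads left out of the totals 1.292. Those of miR-155-5p were then −3.239 and −3.204.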
